A study of Rattus norvegicus with 68 samples.

How the data were processed

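Total RNA of kidney cortex and outer medulla was hybridised to Affymetrix rat arrays with 8799 probe sets, 1 array per tissue sample, per the labels. Each of the 68 columns of the deposited table was matched to its sample by the rat number, tissue, experiment, sex and diet in its title, and 0 columns were left unused. No 2 columns held identical values. Rats of 1 group are separate animals per the labels.

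The authors deposited 1 intensity per probe set and array on a linear scale, with values of 0 for some probe sets. The summary method, the background correction and the scaling behind these intensities are not given in the sources used here. Array medians differed between 7 array sets read from the sample titles, with medians from 22.66 to 106.6, and by 1.05 to 1.15 times within a set. Each set held arrays of 1 tissue and 1 experiment, and the females and males of the gonadectomized outer medulla were in separate sets. Comparisons between experiments are therefore differences of differences within sets, except that of the sex difference between intact and gonadectomized outer medulla. Dim probe sets varied less between arrays of a set than bright ones, and changes near background are understated.

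Gene symbols came from the platform annotation, updated through Entrez gene IDs, of which the reference table held those of 6985 probe sets. Besides 59 control probe sets, 7006 probe sets had 1 symbol, 308 had several and 1426 none here, and only those with 1 symbol were named. Where a gene had several probe sets, the one with the highest mean intensity stood for it, and genes whose named probe set was opposed in sign by another are said to be so. Probe sets of gene families with near-identical members, such as Akr1c13, Cyp2c11 and other cytochrome P450 genes, Ly6i, Klk1b3 and the Slc22a transporters, may read several members and are uncertain in that respect. Renin was not analysed here, since no probe set carried its symbol.

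For comparisons on diet and sex the arrays of a tissue were quantile normalized together, floored at the pooled 20th percentile (4.6 in cortex and 7.62 in outer medulla), and log2 transformed. Control probe sets and the 30% of probe sets with the lowest mean were left out, which kept 6118 probe sets in each tissue. All groups of a tissue were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a variance trend on intensity and 23 residual degrees of freedom in cortex and 21 in outer medulla. The fit pools the spread of all groups, and groups of 2 rats are assumed to vary like the others. The median residual SD of a probe set on the log2 scale was 0.178 in intact Dahl-Iwai, 0.143 in gonadectomized and 0.138 in Sprague-Dawley cortex, and 0.122, 0.154 and 0.147 in outer medulla. A fold against a group at the floor is a lower bound. The salt response within each sex, the difference of the responses between sexes, and the difference between sexes averaged over diets were tested in each experiment. The sex difference was set between intact and gonadectomized Dahl-Iwai rats, and the salt response between intact Dahl-Iwai and Sprague-Dawley rats. Tissues were compared over all arrays normalized together. Probe sets at a Benjamini-Hochberg adjusted p under 0.05 were called.

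Gene lists for pathways and cell types with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Of 141 list calls in the planned comparisons 13 held with the estimated correlation. Not all called lists are named. Groups, comparisons, lists and the rule for naming genes were fixed before the data were examined. The rule took up to 10 genes with the largest rise and 10 with the largest fall among those called, list members as examples, and the 3 genes with the smallest p where fewer than 3 passed, and for the tissues the cell type markers and up to 10 genes each way. The tests in low-salt rats alone and the 1.5-fold minimum were added after the data had been seen. Differences of the female salt response between experiments were also added then. For these, the repeats without a rat are given as a ratio to the count of all rats.

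The fits were tested on simulated noise with 200 of 6118 probe sets changed. For female salt in intact Dahl-Iwai cortex, 41.5% of log2 changes of 0.5 were recovered, 82.7% at 1 and 98.5% at 2. False calls were 6.5 on average over 10 simulations. For male salt in gonadectomized cortex these shares were 49.6%, 87.8% and 98.8%, with 7.5 false calls. Error in real groups of uneven spread was not tested.

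Cortex and outer medulla of 33 rats came from the same animals, by the rat number in the labels. Deviations from the group means correlated between the tissues of a rat with a median of 0.147 over the 33 pairs, and 22 of them lay above 0.1. With the rat as a block the tissue comparison called 5264 probe sets, against 5260 without it.

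Alternatives were the values as deposited without quantile normalization, no filter on dim probe sets, a floor at the 40th percentile, a fit of the compared experiments alone, no variance trend, and leaving out each rat in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.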

Results

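Kidneys of 35 rats were profiled on 68 oligonucleotide arrays, 35 of the cortex and 33 of the outer medulla, the zone between cortex and inner medulla. The rats came from 3 experiments: intact Dahl-Iwai rats, a line bred for blood pressure that is sensitive to salt, gonadectomized Dahl-Iwai rats, and Sprague-Dawley rats, an outbred stock labelled as wild type. Within each experiment males and females were kept on a low or a high salt diet for 14 weeks, and the question named by the series is whether the sexes respond to salt differently. This gave 24 groups of 1 tissue, experiment, sex and diet, 20 of them with 3 rats and 4 with 2. The groups with 2 rats were the high-salt intact Dahl-Iwai females in both tissues, and the high-salt intact Dahl-Iwai males and Sprague-Dawley females in the outer medulla. Array medians ran from 22.66 to 106.6 intensity units, in 7 array sets. Each set held 1 tissue of 1 experiment, and the outer medulla of gonadectomized rats was split by sex into 2 sets. Changes are given as log2 differences with the standard error of the limma fit, and adjusted p values are from limma with Benjamini-Hochberg adjustment. The number of arrays limits the precision of every value. Single rats are named as in the labels, such as rat107.

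**Figure D1:**
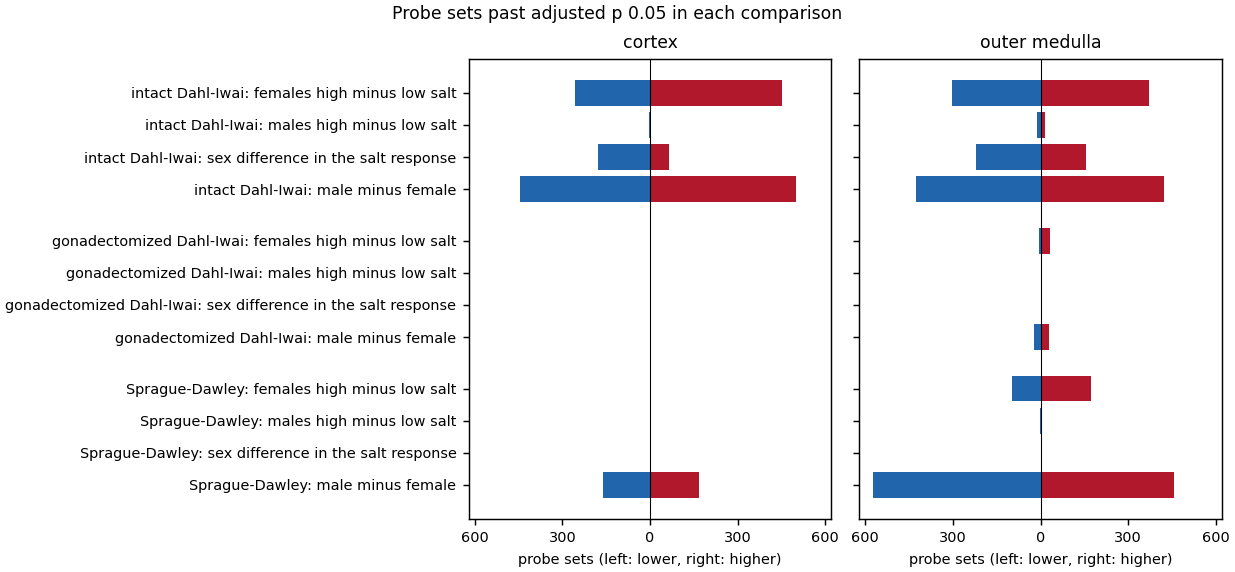
Number of probe sets past adjusted p 0.05 in each comparison on diet or sex, with lower probe sets drawn to the left and higher ones to the right, for cortex and outer medulla. The salt response of intact Dahl-Iwai females reached 452 higher and 256 lower probe sets in cortex and 673 in outer medulla, against 5 and 26 in the males.

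In the cortex of intact Dahl-Iwai females, genes of tubular injury and of the acute-phase response rose on high salt. Havcr1, the kidney injury molecule shed by damaged proximal tubules, rose by 5.21 ± 0.31 or 36.9-fold (adjusted p = 4.21e-12). Its log2 mean went from 4.92 ± 0.08 (SD, n = 3) to 10.12 ± 1.18 (SD, n = 2). The pooled SE understates this spread. Lcn2, the injury marker lipocalin 2, rose by 3.83 ± 0.37 (adjusted p = 7.58e-08). The fibrinogen chains Fgb (3.65 ± 0.22), Fga (3.09 ± 0.25) and Fgg (1.83 ± 0.47) rose together, with adjusted p from 4.21e-12 to 0.0116. Clusterin (Clu, 2.63 ± 0.32, adjusted p = 2.5e-06) and osteopontin (Spp1, 2.50 ± 0.61, adjusted p = 0.00858) rose as well. Further large rises were those of Hspa13 (2.26, adjusted p = 0.000336), Rdh10 (2.25, adjusted p = 0.000271), Tc2n (2.21, adjusted p = 0.00566) and Gpx2 (2.17, adjusted p = 3.07e-05). Igfbp3, a binding protein for insulin-like growth factors, fell by 2.72 ± 0.54 (adjusted p = 0.00131). Egf, made in the thick ascending limb and distal tubule, fell by 1.93 ± 0.36 (adjusted p = 0.000841). Atp5pb, a subunit of mitochondrial ATP synthase, fell by 1.93 ± 0.29 (adjusted p = 3.78e-05). Other falls included Nr4a1 (-1.66, adjusted p = 0.009), Dio1 (-1.18, adjusted p = 0.00863), Dpep1 (-1.15, adjusted p = 0.00416) and Fabp3 (-1.14, adjusted p = 0.00363). In each of these genes except Fgg both high-salt rats lay on the same side of all 3 low-salt rats.

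Of 6118 probe sets 452 were higher and 256 lower in the cortex of these females, which named 431 genes. As deposited 903 passed, of which 796 were higher, so that the share of rises depended on the scaling. Without high-salt rat107, which left 1 rat in that group, the count was 188, and in a fit of the arrays of this experiment alone it was 151.

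Grouped by list, the renal injury and dedifferentiation genes stood out in this comparison. Of 18 measured members 13 rose and none fell, 14 when adjusted over the list, with a median of 1.26 (camera adjusted p = 1e-14, or 0.0152 with an estimated correlation). Examples beyond those above were Anxa2 (2.09 ± 0.30), S100a4 (2.04 ± 0.23) and Timp1 (1.53 ± 0.19). Of 14 MHC and interferon genes 8 rose (8 adjusted over the list, camera adjusted p = 7.3e-07, or 0.0503 with an estimated correlation), among them the immunoproteasome subunits Psmb8 (1.89 ± 0.25) and Psmb9 (1.59 ± 0.19) and the interferon-response gene Irf1 (1.47 ± 0.26). Complement and acute-phase genes rose in 6 of 14 (6 adjusted over the list, camera adjusted p = 1.24e-05, or 0.0152 with an estimated correlation). Leukocyte genes rose in 5 of 13, such as Lgals3 (2.07 ± 0.36), Coro1a (1.92 ± 0.19) and Cxcl10 (1.65 ± 0.27) (5 higher and 2 lower adjusted over the list, camera adjusted p = 0.0106, or 0.111 with an estimated correlation). Cell cycle genes rose in 5 of 16, such as Mcm6 (1.58 ± 0.11) and Tubb5 (1.31 ± 0.19) (6 adjusted over the list, camera adjusted p = 0.00482, or 0.0167 with an estimated correlation). All 16 ribosomal protein genes had values above 0, of which 2 passed (4 adjusted over the list, median 0.31, camera adjusted p = 0.000138, or 0.113 with an estimated correlation). The liver list passed too, with 3 of 10 members higher, Fga (3.09), Fgb (3.65) and Ahsg (0.60) (3 adjusted over the list, median 0.0054, camera adjusted p = 0.021, or 0.0503 with an estimated correlation).

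In the same cortex 3 of 15 sodium transport genes fell (4 adjusted over the list, median -0.31, camera adjusted p = 0.021, or 0.129 with an estimated correlation). They were the sodium-proton exchanger Slc9a3 (-1.03 ± 0.19) and the epithelial sodium channel subunits Scnn1a (-0.65 ± 0.16) and Scnn1b (-0.28 ± 0.078). Of 21 fatty acid oxidation genes 2 fell (5 adjusted over the list, median -0.32, camera adjusted p = 0.0173, or 0.24 with an estimated correlation). The fibrosis list did not pass as a set (adjusted p = 0.0831), although 5 of 22 members rose (6 higher and 2 lower adjusted over the list), including Timp1 (1.53 ± 0.19) and Col1a1 (1.23 ± 0.32).

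**Figure D2:**
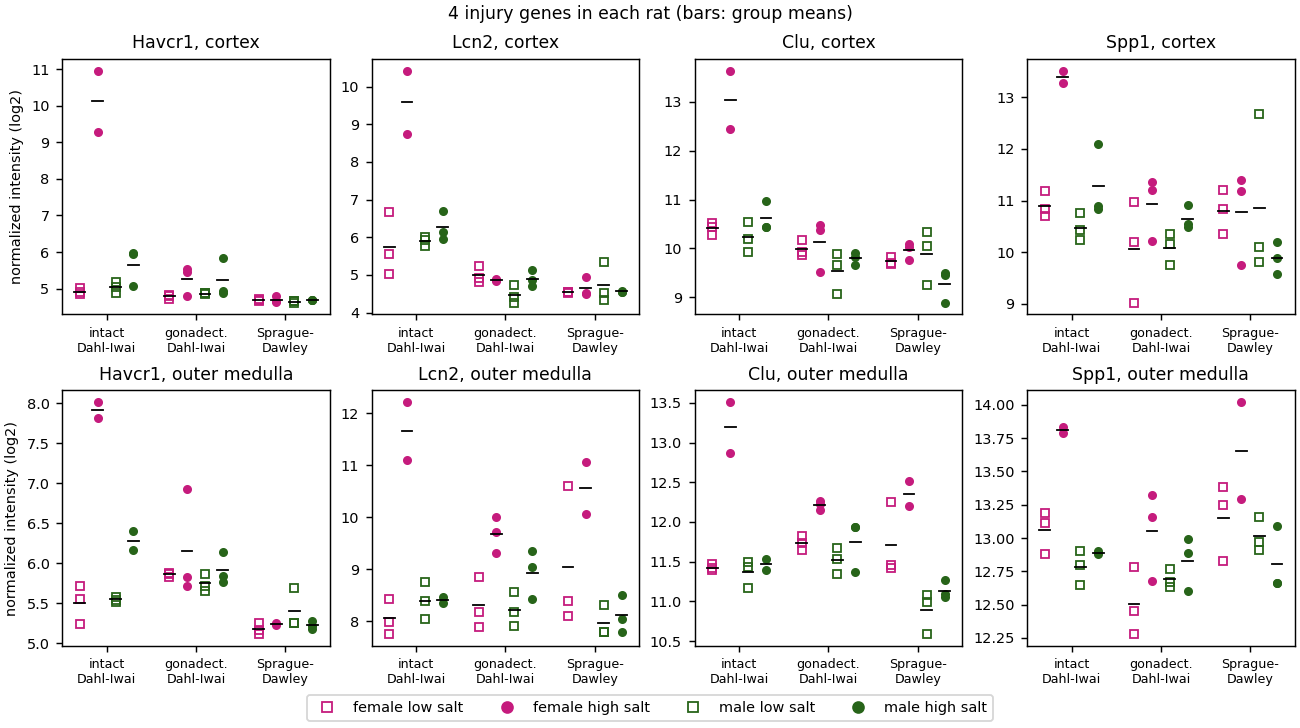
Normalized log2 intensity of Havcr1, Lcn2, Clu and Spp1 in each rat by experiment, sex and diet, with group means as bars, cortex above and outer medulla below. In cortex the high-salt intact Dahl-Iwai females had Havcr1 values of 9.29 and 10.96, against 4.85 to 5.01 in their low-salt group.

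In the cortex of intact Dahl-Iwai males, 5 probe sets passed, 2 higher and 3 lower. They included Cyp2c11, a male-predominant cytochrome P450 (2.34 ± 0.45, adjusted p = 0.0283), and the matrix metalloproteinase Mmp3 (-0.51 ± 0.086, adjusted p = 0.00729). On the values as deposited there were 2 (0 higher and 2 lower), and in a fit of the arrays of this experiment alone 0. Leaving out 1 rat gave 15 without rat109, 11 without rat110, 17 without rat111, 15 without rat112, 15 without rat113 and 11 without rat114. The 18 injury genes had a median of 0.18 with none past the threshold (0 adjusted over the list, camera adjusted p = 0.0339, or 0.612 with an estimated correlation). Havcr1 was at 0.63 ± 0.28, adjusted p = 0.634 and Lcn2 at 0.36 ± 0.33, adjusted p = 1. The complement and acute-phase list also passed as a set in these males, with 0 of 14 members past the threshold (2 higher adjusted over the list, median 0.20, camera adjusted p = 0.0405, or 0.359 with an estimated correlation). So did the cytochrome P450 and arachidonic acid list, with 1 of 17 higher (1 adjusted over the list, median 0.10, camera adjusted p = 0.0339, or 0.359 with an estimated correlation).

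The difference between the male and the female salt response was itself tested, and it passed for 244 probe sets in this cortex, 65 with a more positive response in males and 179 in females. For Havcr1 the male minus female difference in response was -4.58 ± 0.42 (adjusted p = 4.7e-08). Lcn2 (-3.47 ± 0.50, adjusted p = 0.000109), Fgb (-3.04 ± 0.29, adjusted p = 1.12e-07), the macrophage lectin Lgals3 (-2.68 ± 0.48, adjusted p = 0.00106) and Clu (-2.24 ± 0.43, adjusted p = 0.00239) differed in the same direction. In the opposite direction stood Igfbp3 (2.85, adjusted p = 0.0213), Cyp2c11 (2.42, adjusted p = 0.042), Egf (2.04, adjusted p = 0.0157) and Nr4a1 (2.30, adjusted p = 0.0155). Of 18 injury genes 9 responded less in males (12 adjusted over the list, median -1.13, camera adjusted p = 1.88e-10, or 0.0572 with an estimated correlation). For the MHC and interferon list it was 6 of 14 (7 adjusted over the list, camera adjusted p = 8.36e-07, or 0.0572 with an estimated correlation). On the values as deposited 400 (33 higher and 367 lower) probe sets passed. The count was 117 without rat107 and 691 without rat106, and 10 in a fit of the arrays of this experiment alone.

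In the outer medulla of intact Dahl-Iwai females the genes past the threshold included injury, interferon and matrix genes that rose on high salt, and proximal tubule genes that fell. Lcn2 rose by 3.60 ± 0.51 (adjusted p = 2.61e-05) and Havcr1 by 2.41 ± 0.22 (adjusted p = 6.87e-08). Guca2a, the gene of the natriuretic peptide guanylin, rose by 2.47 ± 0.19 (adjusted p = 5.87e-09). The interferon genes Irf7 (2.48 ± 0.40), Cxcl10 (2.42 ± 0.26), Mx1 (2.06 ± 0.25) and Gbp2 (1.79 ± 0.32) rose with adjusted p from 1.05e-06 to 0.00041. The collagen gene Col1a1 (2.18 ± 0.27, adjusted p = 4.86e-06) and the macrophage gene Aif1 (1.83 ± 0.18, adjusted p = 3.05e-07) rose too. The largest fall was that of Gatm, the first enzyme of creatine synthesis (-2.78 ± 0.39, adjusted p = 2.63e-05). The organic anion transporter Slc22a13 (-2.43 ± 0.43, adjusted p = 0.000418), the glutathione synthesis enzyme Gclc (-2.14 ± 0.30, adjusted p = 2.21e-05) and the renal phosphate transporter Slc34a1 (3.99-fold lower, adjusted p = 0.0016) fell. Falls were also seen for Acsm2 (-2.35, adjusted p = 0.00386), Hnmt (-2.27, adjusted p = 1.29e-05), Slc27a2 (-2.11, adjusted p = 0.000296) and Odc1 (-2.03, adjusted p = 0.00065). Both high-salt rats lay beyond all 3 low-salt rats in each of these genes.

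The outer medullary count was 673 probe sets, 371 higher and 302 lower, naming 423 genes. As deposited it was 636 (264 higher and 372 lower). Leaving out 1 rat gave 448 without rat105, 419 without rat106 and 319 without rat107.

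Injury genes rose in 13 of 18 measured members in this tissue (15 adjusted over the list, median 1.04, camera adjusted p = 2.58e-17, or 0.00115 with an estimated correlation), with Clu (1.76 ± 0.21), Anxa1 (1.64 ± 0.18) and Vim (1.44 ± 0.26) among them. MHC and interferon genes rose in 9 of 15 (10 adjusted over the list, camera adjusted p = 5.07e-11, or 0.0419 with an estimated correlation). Leukocyte genes rose in 7 of 13, such as Coro1a (1.39 ± 0.18) and Aif1 (1.83 ± 0.18) (8 adjusted over the list, camera adjusted p = 3.27e-06, or 0.0419 with an estimated correlation). Complement and acute-phase genes rose in 6 of 13, including C1qb (1.75 ± 0.23) (6 adjusted over the list, camera adjusted p = 4.89e-05, or 0.0562 with an estimated correlation). Fibrosis genes rose in 10 of 23, with Timp1 (1.22 ± 0.17) and Col3a1 (0.96 ± 0.12) beside Col1a1 (11 adjusted over the list, camera adjusted p = 0.000101, or 0.0708 with an estimated correlation). Cell cycle genes rose in 4 of 14, such as Mcm6 (1.08 ± 0.10) and Pcna (0.64 ± 0.16) (6 higher and 1 lower adjusted over the list, camera adjusted p = 0.0101, or 0.0419 with an estimated correlation).

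Of 18 proximal tubule transport genes 7 fell in the outer medulla (9 adjusted over the list), with a median of -0.67 (camera adjusted p = 7.84e-09, or 0.0708 with an estimated correlation). Besides Slc34a1 they included the phosphate transporter Slc17a1 (-1.94), the peptide transporter Slc15a2 (-1.65) and the endocytic receptors Lrp2 (-1.51) and Cubn (-1.34). Of 18 genes of amino acid, glucose and ammonia metabolism 10 fell and 1 rose (11 and 1 adjusted over the list, median -1.03, camera adjusted p = 1.36e-07, or 0.105 with an estimated correlation). Examples were the gluconeogenic enzyme Fbp1 (-1.89 ± 0.39), the fructose kinase Khk (-1.66 ± 0.35) and the arginine synthesis enzyme Ass1 (-1.53 ± 0.43). Genes listed as sex-dependent in rat kidney fell in 7 of 19 (8 adjusted over the list, median -0.74, camera adjusted p = 1.59e-06, or 0.0708 with an estimated correlation). Cytochrome P450 and arachidonic acid genes fell in 4 of 17, among them Cyp2d2 (-1.86 ± 0.38), Cyp4f1 (-1.67 ± 0.32) and Cyp4a8 (-1.54 ± 0.23) (6 adjusted over the list, camera adjusted p = 0.000857, or 0.107 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 20, led by Ehhadh (-1.66 ± 0.35) (6 lower and 1 higher adjusted over the list, camera adjusted p = 0.00318, or 0.153 with an estimated correlation). Heat shock and endoplasmic reticulum stress genes fell in 2 of 18 (2 adjusted over the list, camera adjusted p = 0.016, or 0.303 with an estimated correlation). The glutathione list did not pass as a set (adjusted p = 0.137), with 7 members lower, such as Gclc and Gpx3 (-1.34 ± 0.33) and Gclm (-1.28 ± 0.30), and 2 higher (7 and 4 adjusted over the list).

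**Figure D3:**
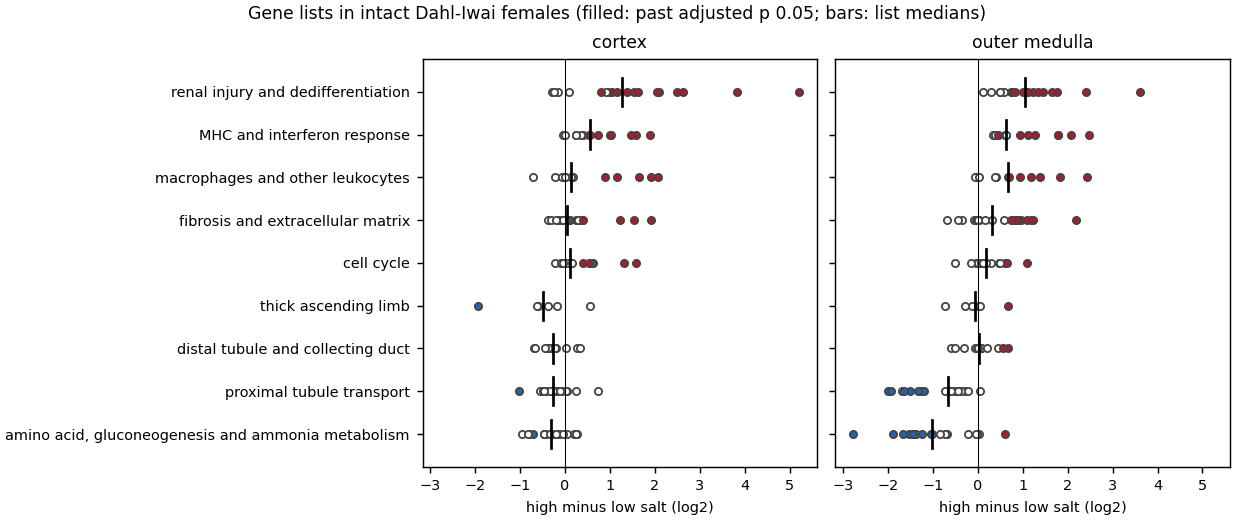
Log2 change with high salt of the measured members of 9 gene lists in intact Dahl-Iwai females, cortex on the left and outer medulla on the right, with filled points past adjusted p 0.05 and bars at list medians. The injury list had medians of 1.26 and 1.04, and the proximal tubule list had a median of -0.67 in outer medulla.

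In the outer medulla of intact Dahl-Iwai males 26 probe sets passed, 15 higher and 11 lower. Genes with the largest changes were the neurofilament gene Nefm (1.14 ± 0.19, adjusted p = 0.00285), the zinc finger gene Zfp426 (-1.06 ± 0.12, adjusted p = 2.08e-05), the kinase Aatk (-1.04 ± 0.13, adjusted p = 3.21e-05) and thymidylate synthase Tyms (-0.71 ± 0.11, adjusted p = 0.00225). Scaling as deposited gave 18 (8 higher and 10 lower), and a fit of the arrays of this experiment alone gave 0. Without high-salt male rat113, which left 1 rat in that group, the count was 99. As sets, complement and acute-phase (median 0.25, camera adjusted p = 0.0326, or 0.514 with an estimated correlation), fibrosis (median 0.09, camera adjusted p = 0.0254, or 0.514 with an estimated correlation) and cytochrome P450 and arachidonic acid genes (median 0.15, camera adjusted p = 0.0326, or 0.514 with an estimated correlation) rose in these males. Distal tubule and collecting duct genes (median -0.27, camera adjusted p = 0.0254, or 0.514 with an estimated correlation) and heat shock genes (median -0.19, camera adjusted p = 0.00848, or 0.514 with an estimated correlation) fell as sets. Of the members of these lists 1 fibrosis gene passed and none of the others. The sex difference in the salt response passed for 376 probe sets, 156 more positive in males and 220 in females. Lcn2 (-3.59 ± 0.71, adjusted p = 0.00261), Irf7 (-3.02 ± 0.57, adjusted p = 0.0017) and Guca2a (-2.46 ± 0.27, adjusted p = 1.35e-05) responded less in males. More positive in males were Slc22a13 (3.05, adjusted p = 0.00287), Cyp2e1 (2.65, adjusted p = 0.0283), Gjb2 (2.50, adjusted p = 0.000387) and Gatm (2.37, adjusted p = 0.00963). Injury genes responded less in males in 10 of 18 (13 adjusted over the list, median -1.01, camera adjusted p = 1.41e-12, or 0.00726 with an estimated correlation). Proximal tubule genes responded more positively in males in 5 of 18 (7 adjusted over the list, median 0.65, camera adjusted p = 5.58e-06, or 0.184 with an estimated correlation). Leaving out 1 rat gave 246 without rat105, 177 without rat107 and 205 without rat114 for this difference, and a fit of this experiment alone gave 205.

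The salt responses of the females were compared between tissues. Of 417 cortical and 414 medullary genes past the threshold among 3471 tested in both, 93 rose and 35 fell in both. Independent lists of these sizes would share 16.5 and 8.84. The arrays of both tissues came from the same rats, so part of the excess may come from the shared animals.

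The sexes were compared over both diets. In the cortex of intact Dahl-Iwai rats, Akr1c13 of the aldo-keto reductases was higher in males by 3.58 ± 0.33 (adjusted p = 3.68e-08). Mannose-binding lectin Mbl1 (2.59 ± 0.21, adjusted p = 2.49e-09), Cyp2c11 (2.53 ± 0.34, adjusted p = 1.08e-05), the organic anion transporter Slco1a1 (2.38 ± 0.31, adjusted p = 7.73e-06) and the organic cation transporter Slc22a2 (1.84 ± 0.22, adjusted p = 1.76e-06) were also higher in males. Higher in females were alcohol dehydrogenase Adh1c (-2.55 ± 0.37, adjusted p = 3.37e-05), Ly6i (-2.72 ± 0.44, adjusted p = 0.000101), carboxypeptidase E, Cpe (-2.09 ± 0.26, adjusted p = 3.95e-06), and ornithine aminotransferase, Oat (-1.74 ± 0.31, adjusted p = 0.000347). Angpt2, a ligand of the endothelial Tie2 receptor, was at background in 6 of 6 males, so that its level in females was at least 4.34-fold higher (adjusted p = 0.00275). Sry on the Y chromosome was at background in 5 of 5 females and in 3 of 6 males (0.77 ± 0.26, adjusted p = 0.0476). Angiotensinogen, Agt, was higher in males (1.48 ± 0.20, adjusted p = 1.27e-05). Of 20 genes listed as sex-dependent 6 were higher and 1 lower in males (6 and 2 adjusted over the list, camera adjusted p = 0.033, or 0.28 with an estimated correlation). Havcr1 had a male minus female difference of -2.18 ± 0.21 over both diets, and 0.11 ± 0.28, adjusted p = 0.972 in the low-salt rats alone. Lcn2 was at 0.16 ± 0.33, adjusted p = 0.96 in those rats and Fgb at -0.39 ± 0.20, adjusted p = 0.4, whereas Akr1c13 was at 3.51 ± 0.44, adjusted p = 3.8e-05 and Adh1c at -2.45 ± 0.50, adjusted p = 0.00574. Cyp2c11 did not pass in the low-salt rats alone (1.32 ± 0.45, adjusted p = 0.152).

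The sex difference of this cortex passed for 946 probe sets, 501 higher and 445 lower in males. The values as deposited gave 1085 (139 higher and 946 lower), which turned the balance towards the females. Without rat107 the count was 466, with the low-salt rats alone it was 151, and in a fit of the arrays of this experiment alone it was 313.

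Sprague-Dawley cortex had 328 probe sets past the threshold for sex, 166 higher and 162 lower in males. Trefoil factor Tff3 (3.92 ± 0.38, adjusted p = 9.39e-08), Cyp2c11 (3.77 ± 0.32, adjusted p = 2.7e-08), Akr1c13 (3.46 ± 0.31, adjusted p = 3.74e-08) and the prolactin receptor Prlr (2.49 ± 0.24, adjusted p = 8.26e-08) were higher in males. Cyp4b1 (-3.20 ± 0.25, adjusted p = 1.16e-08), Slc22a13 (-2.89 ± 0.40, adjusted p = 2.26e-05), Adh1c (-2.38 ± 0.35, adjusted p = 5.77e-05) and extracellular superoxide dismutase Sod3 (-1.75 ± 0.21, adjusted p = 2.59e-06) were higher in females. Of 20 sex-dependent genes 4 were higher and 1 lower in males (6 and 1 adjusted over the list, camera adjusted p = 0.00341, or 0.191 with an estimated correlation). Immediate early genes were higher in males in 5 of 18, such as Jun (1.15 ± 0.17), Dusp1 (0.79 ± 0.18) and Gadd45a (0.79 ± 0.16) (5 adjusted over the list, camera adjusted p = 0.000241, or 0.631 with an estimated correlation), although they fell as a set in the males on high salt (camera adjusted p = 3.04e-06, or 0.257 with an estimated correlation). With the low-salt rats alone the count was 134. Between the strains, 41 genes were higher and 39 lower in males in both, where independent lists would share 8.99 and 6.15, and 7 went in opposite directions.

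In the outer medulla Slc22a2 and Adh1c led the sex differences. Slc22a2 was higher in males by 6.03 ± 0.44 in intact Dahl-Iwai rats (65.3-fold, adjusted p = 1.04e-09) and by 5.83 ± 0.41 in Sprague-Dawley rats (56.9-fold, adjusted p = 2.89e-10). Adh1c was lower in males, at -5.07 ± 0.77, adjusted p = 4.91e-05 and -4.39 ± 0.73, adjusted p = 0.000153. Cyp2c11 (3.75 ± 0.28) and Akr1c13 (3.63 ± 0.33) were higher in intact Dahl-Iwai males. So were retinol-binding protein Rbp4 (3.06 ± 0.48) and vitamin D-binding protein Gc (2.74 ± 0.15). Sprague-Dawley males were higher in Tff3 (5.08 ± 0.36), Akr1c13 (4.17 ± 0.31), Cyp2c11 (4.04 ± 0.26) and Slco1a1 (3.19 ± 0.18) and lower in Cyp4b1 (-3.64 ± 0.26), Slc22a7 (-2.22 ± 0.37) and Ly6i (-2.09 ± 0.47). Of 19 sex-dependent genes 10 were higher and 1 lower in intact Dahl-Iwai males (10 and 2 adjusted over the list, camera adjusted p = 2.02e-08, or 0.103 with an estimated correlation). In Sprague-Dawley rats these counts were 11 and 1 (14 and 1 adjusted over the list, camera adjusted p = 2.89e-08, or 0.143 with an estimated correlation). Proximal tubule transport genes were higher in males in 8 of 18 in intact Dahl-Iwai rats (9 adjusted over the list, camera adjusted p = 8.3e-06, or 0.259 with an estimated correlation). For Sprague-Dawley rats it was 5 of 18 (11 higher and 1 lower adjusted over the list, camera adjusted p = 0.00147, or 0.328 with an estimated correlation). In intact rats both lists include the female fall on high salt (medians -0.74 and -0.67). Thick ascending limb markers were lower in Sprague-Dawley males in 5 of 6 (5 adjusted over the list, median -0.54, camera adjusted p = 0.00147, or 0.143 with an estimated correlation). Distal tubule and collecting duct markers were lower in 7 of 14 (9 adjusted over the list, camera adjusted p = 0.00147, or 0.219 with an estimated correlation). Sodium transport genes were lower in 5 of 14, including Hsd11b2 (-0.92 ± 0.17), Scnn1a (-0.74 ± 0.10) and Scnn1g (-0.52 ± 0.12) (6 adjusted over the list, camera adjusted p = 0.00317, or 0.223 with an estimated correlation).

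Sex differences in the outer medulla passed for 850 probe sets in intact Dahl-Iwai rats, 422 higher and 428 lower in males, and for 1031 in Sprague-Dawley rats, 458 higher and 573 lower. On the values as deposited these were 749 (503 higher and 246 lower) and 1033 (337 higher and 696 lower). Without rat107 the first count was 544, and without rat704 the second was 616. With the low-salt rats alone the first count was 219. The strains shared 144 genes higher and 74 lower in males, where independent lists would share 21 and 25.8, and 13 went in opposite directions.

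**Figure D4:**
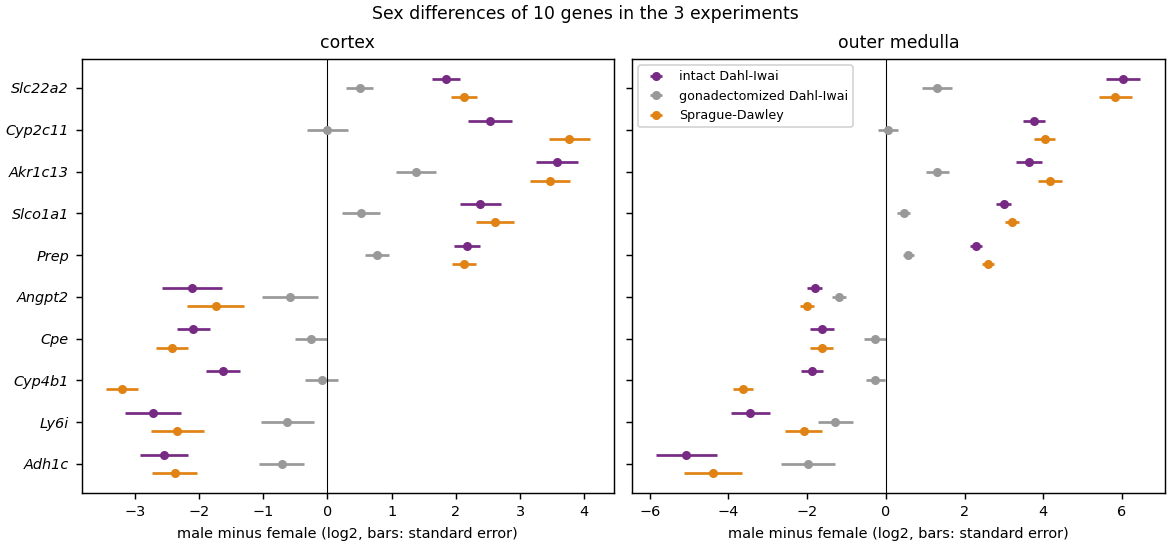
Male minus female log2 difference of 10 genes in cortex and outer medulla of the 3 experiments, with points for the estimates and bars for standard errors. Slc22a2 in outer medulla was 6.03 in intact Dahl-Iwai, 1.30 in gonadectomized Dahl-Iwai and 5.83 in Sprague-Dawley rats.

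Gonadectomized Dahl-Iwai rats had few genes past the threshold for sex, and 2 of their 6 males stood apart. Over genes that differed between Sprague-Dawley sexes, the mean of male-higher minus that of female-higher genes was -1.48 in the cortex of rat7 and -1.80 in that of rat10, against -0.66 to -0.37 in the other males and -2.22 to -1.17 in the females. No fit without both was made, since they stood out by their expression. In the cortex of gonadectomized Dahl-Iwai rats limma called 0 probe sets for sex, with 223 at an unadjusted p under 0.05. Genes with the smallest p were Akr1c13 (1.38, adjusted p = 0.268), Eif2s3 (-0.41, adjusted p = 0.268) and Sult1a1 (-0.69, adjusted p = 0.268). Without 1 rat the count was 1 without rat2, 15 without rat3, 1 without rat6 and 1 without rat10. Cyp2c11 was at background in all gonadectomized rats of both sexes. The difference between the sex differences of intact and gonadectomized Dahl-Iwai rats was tested, and in cortex it passed for 199 probe sets, 72 higher and 127 lower. Mbl1 (2.21 ± 0.28, adjusted p = 3.38e-05), Akr1c13 (2.20 ± 0.45, adjusted p = 0.00497) and Slco1a1 (1.86 ± 0.43, adjusted p = 0.0135) were more male-predominant in the intact rats. Cpe (-1.84 ± 0.36, adjusted p = 0.00333) and Adh1c (-1.84 ± 0.51, adjusted p = 0.0454) were more female-predominant there. The values as deposited gave 284 (45 higher and 239 lower), and without rat106 the count was 514.

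In the outer medulla of gonadectomized rats 53 probe sets passed for sex, 29 higher and 24 lower in males. They included Akr1c13 (1.30, adjusted p = 0.0475), Angpt2 (-1.19, adjusted p = 0.00153), Xdh (-0.60, adjusted p = 0.0486) and Eif2s3 (-0.44, adjusted p = 0.0417). The sexes were in different array sets here, so sex and array set cannot be told apart. Scaling as deposited gave 197 (4 higher and 193 lower), a fit of the arrays of this experiment alone gave 0, and the count was 14 without rat1, 18 without rat2, 24 without rat3, 7 without rat4, 6 without rat5, 92 without rat6, 19 without rat7, 3 without rat8, 8 without rat10 and 85 without rat12. The difference from the intact rats, in which array set and sex of the gonadectomized rats cannot be told apart either, passed for 288 probe sets, 157 higher and 131 lower, led by Slc22a2 (4.73, adjusted p = 2.1e-05), Cyp2c11 (3.70, adjusted p = 1.12e-06), Pzp (2.94, adjusted p = 2.1e-05), Gc (2.71, adjusted p = 3.36e-09) and Slco1a1 (2.54, adjusted p = 1.12e-06), of which Pzp had another probe set with the opposite sign. Lower were Cyp4b1 (-1.60, adjusted p = 0.0113), Cxcl10 (-1.30, adjusted p = 0.00318) and Scd2 (-1.24, adjusted p = 0.00228). Sex-dependent genes were more male-predominant in the intact rats in 7 of 19 (9 adjusted over the list, camera adjusted p = 4.5e-07, or 0.178 with an estimated correlation). As deposited this difference gave 348 (314 higher and 34 lower), and with no filter on dim probe sets 716 (206 higher and 510 lower), which turned the balance. It gave 175 without rat7, 163 without rat107 and 180 without rat114.

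Gonadectomized Dahl-Iwai rats had few probe sets past the threshold for salt. In female cortex limma called 1 probe set, which has no gene symbol here, with 447 at an unadjusted p under 0.05. The named genes with the smallest p were Rhox5 (-0.82, adjusted p = 0.0604), Traf2 (-0.45, adjusted p = 0.0723) and Mmrn1 (-0.47, adjusted p = 0.09). As deposited there was no call, and the count was 4 without rat1, 5 without rat2, 26 without rat3, 0 without rat4, 3 without rat5 and 2 without rat6. In male cortex limma called 0 (251 unadjusted), with Id1 (-0.99, adjusted p = 0.419), Eloa (0.36, adjusted p = 0.717) and Rpl18 (0.45, adjusted p = 0.732) first, and 1 without rat7. The sex difference in the cortical response was called for 0 (212 unadjusted), with Eloa (0.48, adjusted p = 1), Eif2d (-1.07, adjusted p = 1) and Pacsin2 (0.45, adjusted p = 1) first, and 1 without rat1 and 5 without rat3. In female outer medulla 37 probe sets passed, 33 higher and 4 lower. Among them were the leucine zipper gene Tsc22d1 (1.11 ± 0.17, adjusted p = 0.00288), Col1a1 (1.03 ± 0.24, adjusted p = 0.0468), sterol carrier protein Scp2 (0.83 ± 0.16, adjusted p = 0.0231) and Gclc (-1.12 ± 0.26, adjusted p = 0.0483). Injury genes had a median of 0.33 with none past the threshold (7 adjusted over the list, camera adjusted p = 3.28e-05, or 0.29 with an estimated correlation). Proximal tubule genes had a median of -0.55 with none past it (3 lower and 1 higher adjusted over the list, camera adjusted p = 0.0017, or 0.505 with an estimated correlation). The count was 94 (92 higher and 2 lower) as deposited, 0 in a fit of the arrays of this experiment alone, and 4 without rat1, 96 without rat3, 11 without rat4 and 10 without rat5. In male outer medulla 2 probe sets without a gene symbol here passed, with Ins2 (-0.51, adjusted p = 0.145), Cyp2b15 (-0.43, adjusted p = 0.145) and Hlf (0.31, adjusted p = 0.17) first among named genes, and the count was 4 without rat9, 4 without rat11 and 7 without rat12, or 5 (4 higher and 1 lower) as deposited. The sex difference in this response was called for 0 (388 unadjusted), with Zfp111 (-0.29, adjusted p = 0.181), Aqp1 (-1.04, adjusted p = 0.181) and Myo1c (-0.78, adjusted p = 0.252) first, 5 (0 higher and 5 lower) as deposited, and 10 without rat3, 1 without rat5, 3 without rat7, 1 without rat9 and 1 without rat12.

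Sprague-Dawley rats had few cortical genes past the threshold for salt. In females 3 probe sets rose, with the zinc alpha2-glycoprotein gene Azgp1 (0.96 ± 0.14, adjusted p = 0.000643) as the named gene, followed by Scd2 (2.02, adjusted p = 0.127) and Dbp (0.59, adjusted p = 0.419), of which Scd2 had another probe set with the opposite sign. In a fit of this experiment alone the count was 0, and without rat701 it was 5. In males limma called 0 (476 unadjusted), with Gdf15 (-0.93, adjusted p = 0.076), Pex11a (0.84, adjusted p = 0.076) and Cdkn1b (-0.66, adjusted p = 0.076) first and 3 without rat707, 7 without rat708, 14 without rat709, 1 without rat711 and 6 without rat712. As deposited there were 3 (1 higher and 2 lower). As sets, without a member past the threshold, proximal tubule transport (median 0.28, camera adjusted p = 0.00491, or 0.32 with an estimated correlation), cytochrome P450 and arachidonic acid (median 0.34, camera adjusted p = 2.43e-05, or 0.0542 with an estimated correlation) and amino acid, glucose and ammonia metabolism genes (median 0.26, camera adjusted p = 0.00491, or 0.32 with an estimated correlation) rose in these males. Immediate early genes (median -0.41, camera adjusted p = 3.04e-06, or 0.257 with an estimated correlation), thick ascending limb markers (median -0.33, camera adjusted p = 0.0164, or 0.341 with an estimated correlation), heat shock genes (median -0.15, camera adjusted p = 0.021, or 0.32 with an estimated correlation) and ribosomal protein genes (median -0.11, camera adjusted p = 0.0346, or 0.426 with an estimated correlation) fell. The sex difference in the cortical response passed for Por, the cytochrome P450 reductase (1.60 ± 0.28, adjusted p = 0.0282), as the 1 call, followed by Azgp1 (-0.93, adjusted p = 0.122) and Acsm3 (1.64, adjusted p = 0.253). As sets, proximal tubule transport (0.33, camera adjusted p = 0.0465, or 0.638 with an estimated correlation) and cytochrome P450 and arachidonic acid genes (0.19, camera adjusted p = 0.000257, or 0.131 with an estimated correlation) responded more positively in males by median. Immediate early genes (-0.36, camera adjusted p = 0.000109, or 0.355 with an estimated correlation) and thick ascending limb markers (-0.29, camera adjusted p = 0.049, or 0.638 with an estimated correlation) responded more negatively. As deposited it was 2 (1 higher and 1 lower), and in a fit of this experiment alone 0. That count was 3 without rat701, 4 without rat702, 3 without rat703, 0 without rat704, 0 without rat705, 0 without rat707, 2 without rat708, 4 without rat709, 0 without rat710 and 0 without rat711. In female outer medulla 270 probe sets passed, 173 higher and 97 lower, of which 71 changed by at least 1.5-fold. Higher were the desaturase Scd2 (0.90 ± 0.24, adjusted p = 0.0361) and the mast cell tryptase Tpsb2 (0.80 ± 0.13, adjusted p = 0.00449), and lower were Gatm (-1.58 ± 0.39, adjusted p = 0.0319) and the immune checkpoint gene Vsir (-1.12 ± 0.18, adjusted p = 0.00407). This count was 698 without rat701, 47 without rat702, 23 without rat703, 94 without rat704 and 1 without rat706, and as deposited it was 296 (9 higher and 287 lower), where the median of all probe sets lay at -0.101. In a fit of the arrays of this experiment alone 3 passed. In male outer medulla 5 passed, including Agt (-0.68 ± 0.12, adjusted p = 0.0333) and the guanylate cyclase gene Gucy1b2 (-0.44 ± 0.074, adjusted p = 0.0238), and the count was 8 without rat707, 8 without rat708, 1 without rat709, 2 without rat710, 1 without rat711 and 18 without rat712, or 4 (0 higher and 4 lower) as deposited and 0 in a fit of this experiment alone. The sex difference there was called for 0 (438 unadjusted), with Sart1 (0.38, adjusted p = 0.198), Casp2 (0.62, adjusted p = 0.198) and Tsc22d1 (-1.09, adjusted p = 0.198) first and 8 without rat701, 2 without rat702, 18 without rat704, 2 without rat707 and 1 without rat712.

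The salt response averaged over sexes was more positive in intact Dahl-Iwai than in Sprague-Dawley cortex for Havcr1 (2.89 ± 0.29, adjusted p = 4.1e-07), Lcn2 (2.12 ± 0.34, adjusted p = 0.000903), Fgb (2.07 ± 0.20, adjusted p = 4.1e-07) and Clu (1.70 ± 0.30, adjusted p = 0.00207). It was more negative for the renal dipeptidase Dpep1 (-0.96 ± 0.24, adjusted p = 0.0348). Of 18 injury genes 7 differed (14 adjusted over the list, median 0.76, camera adjusted p = 1.17e-14, or 0.00669 with an estimated correlation). The difference passed for 80 probe sets, 69 higher and 11 lower, and the count was 122 without rat103, 427 without rat106, 49 without rat702 and 136 without rat709. In outer medulla it passed for 24, 21 higher and 3 lower, led by Guca2a (1.89, adjusted p = 1.65e-06), Col1a1 (1.64, adjusted p = 0.00272) and Havcr1 (1.63, adjusted p = 0.000175), and the count was 37 without rat103, 40 without rat113 and 59 without rat701. On the values as deposited these differences gave 132 (127 higher and 5 lower) and 44 (43 higher and 1 lower), and in a fit of the arrays of both experiments alone 25 and 11.

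Outer medulla and cortex differed in 5260 of 6118 probe sets, 2884 higher and 2376 lower in the outer medulla, which named 3099 genes, 1717 of them with the same sign in all 3 experiments. The thick ascending limb cotransporter Slc12a1 (2.17 ± 0.085), the potassium channel Kcnj1 (1.87 ± 0.082) and the water channel Aqp2 (2.34 ± 0.086) were higher in outer medulla. The proximal tubule glucose transporter Slc5a2 (-6.26 ± 0.14), the bicarbonate transporter Slc4a4 (-6.34 ± 0.11), the distal cotransporter Slc12a3 (-3.94 ± 0.12) and the podocyte gene Ptpro (-1.76 ± 0.052) were lower. Umod did not pass (0.049 ± 0.048, adjusted p = 0.335), at 0.80 in intact and -0.62 in gonadectomized rats. The largest rises were Fst (6.39), Tesc (6.07) and Fabp4 (5.38). The lowest were Klk1b3 (-6.67), Slc4a4 and Slc5a2. Proximal tubule transport genes were lower in 16 and higher in 2 of 19 (16 and 2 adjusted over the list, camera adjusted p = 0.000313, or 0.294 with an estimated correlation). Thick ascending limb markers were higher in 5 of 6 (adjusted p = 0.0566). Tissue and array set cannot be told apart. Here ± and p leave out the spread between experiments, in which Slc4a4 ran from -8.6 in gonadectomized to -3.6 in intact rats. As deposited 5769 passed (4942 higher and 827 lower).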

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

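The tests of liver RNA, of a single outlying rat, of the share of outer stripe, of exchanged or wrong sex labels and of array noise were chosen only after the result was seen, as were the differences of the female salt response between experiments. The results below stood out because the response to salt, or the difference between sexes, was itself different between sexes, experiments or strains in a test of that difference with limma. No search for outlying rats was made over all results, since groups held 2 or 3 rats.

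In intact Dahl-Iwai cortex the salt response differed between sexes for 244 probe sets (400 (33 higher and 367 lower) as deposited, 117 without rat107 and 691 without rat106). It was more positive in males for Igfbp3 (2.85), Cyp2c11 (2.42) and Nr4a1 (2.30) and more negative for Hspa13 (-3.13), Lcn2 (-3.47) and Havcr1 (-4.58). In Sprague-Dawley cortex this difference passed for 1 probe set, that of Por (1.60). Without a rat the count ran from 0 to 4 (3 without rat701, 4 without rat702, 3 without rat703, 0 without rat704, 0 without rat705, 0 without rat707, 2 without rat708, 4 without rat709, 0 without rat710 and 0 without rat711), it was 2 (1 higher and 1 lower) as deposited, and in 45 of 100 exchanges of the sex labels at least as many passed, up to 115, so that chance is not excluded. Such exchanges carry the sex difference itself (328 probe sets) into this comparison, a structure of the samples that can raise their counts. In intact Dahl-Iwai outer medulla it passed for 376 probe sets (246 without rat105, 177 without rat107 and 205 without rat114), with Slc22a13 (3.05), Cyp2e1 (2.65) and Gjb2 (2.50) more positive in males and Guca2a (-2.46), Irf7 (-3.02) and Lcn2 (-3.59) more negative. No split of the samples was run for the sex differences in response of intact Dahl-Iwai rats, since each included a group of 2 rats.

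The sex difference itself differed between intact and gonadectomized Dahl-Iwai cortex for 199 probe sets (284 (45 higher and 239 lower) as deposited, 514 without rat106). In 2 of 100 exchanges of the sex labels as many passed, with 199 against at most 251 in the others, which excludes chance at the 0.05 level. More male-predominant in the intact rats were Cyp2c11 (2.53), Mbl1 (2.21) and Akr1c13 (2.20), and less so Cpe (-1.84), Fgb (-1.92) and Havcr1 (-2.20). Cyp2c11 and Fgb were at background in the gonadectomized cortex, so their values rest on the intact rats. Havcr1 and Fgb include the intact females' salt response: in low-salt intact rats sex differences were Havcr1 (0.11, adjusted p = 0.972) and Fgb (-0.39, adjusted p = 0.4). In outer medulla 288 passed (348 (314 higher and 34 lower) as deposited, 716 (206 higher and 510 lower) with no filter on dim probe sets, 175 without rat7, 163 without rat107 and 180 without rat114), and 8 of 100 exchanges gave as many, up to 620, so that chance is not excluded. Here too the exchanges carry the sex difference itself (850 in intact rats). The gonadectomized sexes were in different array sets there, so sex and array set cannot be told apart. Leading genes were Slc22a2 (4.73), Cyp2c11 (3.70) and Pzp (2.94) and Scd2 (-1.24), Cxcl10 (-1.30) and Cyp4b1 (-1.60). Another probe set of Pzp had the opposite sign, and Cxcl10 includes the intact females' salt rise (2.42).

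The salt response averaged over sexes differed between intact Dahl-Iwai and Sprague-Dawley cortex for 80 probe sets (132 (127 higher and 5 lower) as deposited, 122 without rat103, 427 without rat106, 49 without rat702 and 136 without rat709). Of 100 exchanges of the diet labels 5 gave as many, up to 117, so that chance is not excluded. It was higher in Dahl-Iwai rats for Havcr1 (2.89), Lcn2 (2.12) and Fgb (2.07) and lower for Pdk2 (-0.77), Scly (-0.82) and Dpep1 (-0.96). In outer medulla 24 passed (44 (43 higher and 1 lower) as deposited, 37 without rat103, 40 without rat113 and 59 without rat701), with Guca2a (1.89), Col1a1 (1.64) and Havcr1 (1.63) higher and Zfp426 (-0.54) and Aatk (-0.70) lower. There 13 of 100 exchanges gave as many, up to 355, so that chance is not excluded. These exchanges carry the salt response itself (673 probe sets in intact Dahl-Iwai and 270 in Sprague-Dawley females) into the comparison.

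For females alone, the cortical salt response differed between intact and gonadectomized Dahl-Iwai rats for 188 probe sets, 152 more positive and 36 more negative in the intact (285 (264 higher and 21 lower) as deposited). As a ratio to the count of all rats, here and below, it was 0.654 times without rat107 and 3.19 times without rat106. The leading genes were Havcr1 (4.73), Lcn2 (3.96) and Fgb (3.65) and Egf (-1.97), Atp5pb (-2.09) and Igfbp3 (-2.88), and the injury list had a median of 1.09 (camera adjusted p = 6.3e-12, or 0.0252 with an estimated correlation). Against Sprague-Dawley females 168 passed, 144 more positive and 24 more negative (264 (249 higher and 15 lower) as deposited, 0.619 times without rat107 and 3.43 times without rat106), led by Havcr1 (5.20), Lcn2 (3.71) and Fgb (3.55) and Azgp1 (-1.27), Egf (-1.85) and Atp5pb (-1.91). In outer medulla the difference from gonadectomized females passed for 78, 63 more positive and 15 more negative (64 (36 higher and 28 lower) as deposited, 0.615 times without rat104, 0.526 times without rat107, 0.526 times without rat2 and 0.654 times without rat5), led by Irf7 (2.40), Guca2a (2.14) and Havcr1 (2.11) and Gjb2 (-1.47), Cnr1 (-1.54) and Hnmt (-2.07), with an injury list median of 0.78 (camera adjusted p = 2.1e-10, or 0.0095 with an estimated correlation). The difference from Sprague-Dawley females passed for 265, 192 more positive and 73 more negative (291 (250 higher and 41 lower) as deposited, 0.608 times without rat105, 0.543 times without rat106, 0.438 times without rat107 and 0.343 times without rat706), led by Irf7 (3.05), Guca2a (2.98) and Col1a1 (2.60) and Fbp1 (-2.06), Haao (-2.09) and Slc34a1 (-2.28). No split of the samples was run for these, since each included a group of 2 rats.

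The first pattern is the rise of injury genes in the high-salt intact Dahl-Iwai females. RNA of liver or plasma as the whole cause is argued against, since 7 liver genes outside the injury and acute-phase lists had a median of -0.0827 in cortex, with 3 of them above 0 and the highest at 0.60. The whole liver list passed in cortex (camera adjusted p = 0.021, or 0.0503 with an estimated correlation), with 3 of 10 members higher: the acute-phase genes Fga and Fgb, and Ahsg (0.60). A smaller share of such RNA stays open. A single outlying rat is argued against as well, since in each rat and tissue at least 13 of 18 injury genes lay above the highest low-salt rat. Those counts were 13 and 14 in cortex and 15 and 17 in outer medulla, with medians of 0.892 and 1.60 in cortex and 0.908 and 0.991 in outer medulla. An effect of high salt in intact females of this line may underlie the pattern, as a hypothesis that rests on the 2 high-salt rats.

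A second pattern is the fall of proximal tubule genes in outer medulla of the same females. The list fell in gonadectomized females too, but less (median -0.55, against -0.67). Quantile normalization is argued against, since the list median was -0.781 on the values as deposited. Their own scaling is not known and was not tested. Less outer stripe, which holds the straight proximal tubule, stays open: the 6 inner stripe and descending limb genes had a median of -0.342 (SE 0.186 over the genes), which cannot decide. Lower expression in proximal tubule cells with high salt may also account for it and was not tested.

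The third pattern is that 2 gonadectomized males, rat7 and rat10, had expression in the range of the gonadectomized females over genes that differed between Sprague-Dawley sexes by at least 1 on the log2 scale. The score, the mean of male-higher minus that of female-higher genes (15 and 22 in cortex, 58 and 19 in outer medulla), was -1.48 and -1.80 in their cortex and -0.92 and -1.31 in their outer medulla, against -2.22 to -1.17 and -1.47 to -0.72 in the females. An exchange of labels with females is argued against, since 0 of the female scores lay above the median male. A wrong sex label is argued against by the X-linked genes Eif2s3 and Ddx3x. Their mean over both tissues was 9.625 in rat7 and 9.64 in rat10, against 9.656 in the 4 other gonadectomized males of the same array sets. With the mean difference of 0.37 between females and males of the other experiments, the levels fell short of that of a female by 0.401 and 0.386 (SE 0.109). Noise of single arrays as the whole cause is argued against, since the scores of the 6 males correlated between their arrays of both tissues by 0.924 (exact one-sided permutation p = 0.00833, where 0.00139 is the smallest possible). Both tissues had entered the choice of this pattern, so that this p is not an independent one. Over the probe sets of the tissue comparison the deviations from the group mean correlated between the tissues by 0.311 in rat7 and 0.319 in rat10, against a median of 0.147 over the 33 rats. A difference in hormone levels between the gonadectomized males may also account for it and was not tested.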

How the results depend on the processing

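The minimum of 1.5-fold, the low-salt rats alone and the differences of the female salt response between experiments were tests chosen only after the data were seen, and the other alternatives were planned. The counts of the salt response in intact Dahl-Iwai females, of the sex differences in intact and Sprague-Dawley rats and of the tissues stayed within 1.5 times of their values under each change of scaling, filter, floor and trend. The tissue count ran from 4872 to 6845 over its alternatives, including each experiment alone and without it. Of the gene values named here 222 kept direction and side of the threshold on the values as deposited, where 9 no longer passed and 4 did so anew. With no filter on dim probe sets 232 did so and 6 no longer passed, with the floor at the 40th percentile 223 and 7, and without the variance trend 237 and 2. In a fit of the compared experiments alone 176 did so and 63 no longer passed. That fit has fewer arrays and takes the spread of those experiments alone, and which of the 2 lowered the counts was not tested. Genes that the filter left out under an alternative, such as Ahsg on the values as deposited, have no value there. Over the repeats that left out a rat, 2114 gene values were kept and 209 no longer passed. Havcr1 turned from negative to 0.11 for sex in the low-salt rats of intact Dahl-Iwai cortex. Agt went to 0 for salt in Sprague-Dawley males of outer medulla with the floor at the 40th percentile, where its values lay at that floor. Sry in gonadectomized cortex, never past the threshold, was at 0.043 in the low-salt rats alone and between -0.025 and 0.015 without a rat. Of 141 calls of gene lists over the planned comparisons, 121 held on the values as deposited, 122 without the filter, 132 with the higher floor and 134 with all probe sets of a gene, but 13 with an estimated correlation. With the rat as a replicate block the tissue count was 5264 against 5260, 5212 of them shared with the same sign, and it changed no other call, since the other comparisons are between rats. Signal over background limits what can be seen of dim genes, and lone rats left in a group are assumed to vary like the others.

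The counts below moved by more than 1.5 times, and the cause was not tested except where a minimum size lowered them. With the deposited scaling the cortex counts were 2 for male salt and 400 for the sex difference in response in intact Dahl-Iwai rats, and 0 for female salt in gonadectomized rats. The others in cortex were 3 for male salt and 2 for the sex difference in response in Sprague-Dawley rats, and 132 for salt between strains, 285 for female salt between intact and gonadectomized rats and 264 for female salt between strains. With the deposited scaling the outer medulla counts were 94 for female salt, 5 for male salt, 5 for the sex difference in response and 197 for sex in gonadectomized rats, and 2 for the sex difference in response in Sprague-Dawley rats. The others in outer medulla were 44 for salt between strains. With no filter on dim probe sets the cortex counts were 20 for male salt in intact Dahl-Iwai rats, and 1 for sex in gonadectomized rats. The others in cortex were 7 for female salt and 8 for the sex difference in response in Sprague-Dawley rats. With no filter on dim probe sets the outer medulla counts were 84 for male salt in intact Dahl-Iwai rats, and 118 for female salt, 5 for male salt, 3 for the sex difference in response and 344 for sex in gonadectomized rats. The others in outer medulla were 4 for the sex difference in response in Sprague-Dawley rats, and 716 for sex between intact and gonadectomized rats and 49 for salt between strains. With the floor at the 40th percentile the cortex counts were 11 for male salt in intact Dahl-Iwai rats, and 14 for female salt in gonadectomized rats. The others in cortex were 4 for the sex difference in response in Sprague-Dawley rats. With the floor at the 40th percentile the outer medulla counts were 46 for male salt in intact Dahl-Iwai rats, and 117 for female salt, 3 for the sex difference in response and 204 for sex in gonadectomized rats. The others in outer medulla were 450 for female salt and 3 for the sex difference in response in Sprague-Dawley rats, and 57 for salt between strains and 127 for female salt between intact and gonadectomized rats.

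In a fit of the compared experiments alone the cortex counts were 151 for female salt, 0 for male salt, 10 for the sex difference in response and 313 for sex in intact Dahl-Iwai rats, and 0 for female salt and 1 for sex in gonadectomized rats. The others in cortex were 0 for female salt and 0 for the sex difference in response in Sprague-Dawley rats, and 25 for salt between strains and 96 for female salt between strains. In a fit of the compared experiments alone the outer medulla counts were 0 for male salt and 205 for the sex difference in response in intact Dahl-Iwai rats, and 0 for female salt, 1 for male salt and 0 for sex in gonadectomized rats. The others in outer medulla were 3 for female salt, 0 for male salt and 1 for the sex difference in response in Sprague-Dawley rats, and 11 for salt between strains. Without the variance trend the outer medulla counts were 18 for sex in gonadectomized rats. With a minimum of 1.5-fold the cortex counts were 424 for female salt and 299 for sex in intact Dahl-Iwai rats, and 166 for sex in Sprague-Dawley rats. The others in cortex were 129 for sex between intact and gonadectomized rats. With a minimum of 1.5-fold the outer medulla counts were 14 for male salt and 365 for sex in intact Dahl-Iwai rats, and 21 for female salt, 1 for male salt and 7 for sex in gonadectomized rats. The others in outer medulla were 71 for female salt, 2 for male salt and 349 for sex in Sprague-Dawley rats, and 138 for sex between intact and gonadectomized rats. In the low-salt rats alone the cortex counts were 151 for sex in intact Dahl-Iwai rats, and 134 for sex in Sprague-Dawley rats. In the low-salt rats alone the outer medulla counts were 219 for sex in intact Dahl-Iwai rats, and 9 for sex in gonadectomized rats.

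Leaving out each rat in turn gave, in cortex, 188 to 1032 for female salt, 117 to 691 for the sex difference in response, 466 to 1247 for sex and 11 to 17 for male salt in intact Dahl-Iwai rats. It gave 0 to 26 for female salt, 0 to 5 for the sex difference in response, 0 to 15 for sex and 0 to 1 for male salt in gonadectomized rats. It gave 2 to 5 for female salt, 0 to 4 for the sex difference in response, 255 to 354 for sex and 0 to 14 for male salt in Sprague-Dawley rats. It gave 152 to 514 for sex between intact and gonadectomized rats and 49 to 427 for salt between strains. Leaving out each rat in turn gave, in outer medulla, 319 to 738 for female salt, 177 to 511 for the sex difference in response, 544 to 1005 for sex and 28 to 99 for male salt in intact Dahl-Iwai rats. It gave 4 to 96 for female salt, 0 to 10 for the sex difference in response, 3 to 92 for sex and 2 to 7 for male salt in gonadectomized rats. It gave 1 to 698 for female salt, 0 to 18 for the sex difference in response, 616 to 1190 for sex and 1 to 18 for male salt in Sprague-Dawley rats. It gave 163 to 432 for sex between intact and gonadectomized rats and 16 to 59 for salt between strains. For the added differences of the female salt response, leaving out each rat gave 0.654 to 3.19 times the cortex count between intact and gonadectomized rats, 0.619 to 3.43 times that between strains, and 0.526 to 1.36 and 0.343 to 1.46 times the same counts in outer medulla. In cortex of intact Dahl-Iwai females the lowest count came without rat107 and the highest without rat106.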

Other observations

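The test of the X-linked genes against the array set was chosen only after the result was seen, and the splits of the samples were planned.

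The salt response of gonadectomized Dahl-Iwai females in outer medulla resembled that of the intact females in direction, and less so in cortex. Of 423 genes past the threshold in the intact females 373 had the same sign in the gonadectomized ones, with a median of 0.299 in that direction, against a median size of 0.83 in the intact females. Among 22 genes past the threshold in gonadectomized females 8 rose and 1 fell in both, where independent lists would share 1.3 and 0.104. The correlation of the changes was 0.624 across genes, which are not independent replicates. In cortex 243 of 431 genes had the same sign, with a median of 0.0184 in that direction and a correlation of 0.143. The size of the response nevertheless differed in outer medulla, where 78 probe sets passed for the difference between intact and gonadectomized females. The rats of both experiments were different animals on different arrays.

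Eif2s3 and Ddx3x, which lie on the X chromosome, were lower in males in each of the 6 comparisons of tissue and experiment. The mean of both differed by -0.398 in cortex of intact Dahl-Iwai rats (males minus females on the log2 scale, exact permutation p = 0.00216, adjusted p = 0.00432). It differed by -0.287 in gonadectomized (exact p = 0.00866, adjusted p = 0.00866) and -0.272 in Sprague-Dawley cortex (exact p = 0.00216, adjusted p = 0.00432). In outer medulla it was -0.428 (exact p = 0.00794, adjusted p = 0.00866), -0.413 (exact p = 0.00216, adjusted p = 0.00432) and -0.340 (exact p = 0.00433, adjusted p = 0.00649) in the same order. In gonadectomized outer medulla the sexes were in different array sets. The array set as the whole cause of the lower level in gonadectomized males is argued against by the cortical value of -0.287, where both sexes shared an array set. Sry did not pass for sex in gonadectomized cortex (-0.011 ± 0.25, adjusted p = 1) or in Sprague-Dawley cortex (-0.012 ± 0.25, adjusted p = 1) and was too dim to be tested in outer medulla.

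Other splits of the rats were counted where each side of a comparison held at least 3 rats, taken over both diets for sex and over both sexes for the strains. They were not counted for the salt responses that included a group of 2 rats, those of intact Dahl-Iwai females, of intact Dahl-Iwai males in outer medulla and of Sprague-Dawley females in outer medulla, nor for sex differences between such responses. With 3 rats against 3 there are 10 splits, too few for a share under 0.05. For salt, these gave at least as many probe sets in 6 splits in intact Dahl-Iwai male cortex (5 against at most 18 in the others), 5 in gonadectomized female cortex (1 against 29), 10 in gonadectomized male cortex (0 against 1), 1 in Sprague-Dawley female cortex (3 against 1) and 10 in Sprague-Dawley male cortex (0 against 10). In outer medulla they did so in 1 split for gonadectomized females (37 against 4), 2 for gonadectomized males (2 against 5) and 1 for Sprague-Dawley males (5 against 2). A real count of 0 is reached by each split, so that these splits say nothing there. Whether the higher counts of other splits, such as the 29 in gonadectomized female cortex, come from structure among rats beyond diet was not tested.

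With the sex labels exchanged among rats of 1 diet, chance was excluded at the 0.05 level for the sex difference of cortex in intact Dahl-Iwai rats (946 against at most 561, 1 of 100 splits) and in Sprague-Dawley rats (328 against 115, 1 of 100). In outer medulla it was excluded in intact Dahl-Iwai rats (850 against 838, 1 of 60), Sprague-Dawley rats (1031 against 1093, 2 of 100) and gonadectomized rats (53 against 47, 1 of 100), where the real split is also that of the array sets. Where no probe set passed, all 100 of 100 splits give at least as many by construction, so the splits say nothing on chance. This holds for the sex difference in gonadectomized cortex (0 against at most 6) and for the sex difference in the salt response of gonadectomized cortex (0 against 11) and outer medulla (0 against 47). With the tissues exchanged within rats, 5260 probe sets stood against at most 2920, in 1 of 100 splits, which excludes chance.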
